A study of Homo sapiens with 24 samples.

How the data were processed

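Total RNA from Rh30 cells of 8 transfection groups, 3 per group, was measured on 24 Agilent 1-colour arrays (design 028004) with 62976 spots each, of which 4259 are controls. Per the file headers, the scanner files were written by Feature Extraction 10.7.3.1, whereas the submitters' processing notes name 10.5.1.1. The deposited scanner files give the processed signal of each spot as an intensity after local background subtraction and spatial detrending, without normalisation between arrays, together with the median signal and the median background of the spot as intensities. The deposited files also hold yes-or-no marks per spot, of the kind "other", for signal well above background, saturation and outlying spots. The deposited values of the series are on the log2 scale. All the columns share 1 set of quantiles (median 7.32), and each follows the log2 of that array's processed signal, with r of about 0.999, so they were read as quantile-normalised log2 signal; the tool behind them is not stated.

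The processed signal of spots marked as outliers was left out, the remaining spots of a probe were averaged on the log2 scale, and the 75th percentile of each array was subtracted. No spot was saturated, and 60 probes without a value on some array were dropped. A probe counted as well above background on an array when at least 0.5 of its spots were marked so, and was kept when this held on all 3 arrays of at least 1 group, which left 33921 probes, 29617 of them well above background on all 24 arrays. The probes' RefSeq accessions gave a current symbol for 26364 of 42405 probes and 19796 genes. The 3059 probes with Ensembl transcript names and 6745 for long intergenic RNAs kept the name in the files. Where several probes had 1 gene name, the probe with the highest mean signal stood for the gene. The text gives the others for some of the genes where they differ. This left 27831 genes, 59.8% of them named by symbol.

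limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8) fitted 1 mean per group over all 24 arrays, with 16 residual degrees of freedom and a moderated variance. Contrasts gave each siRNA group against NT, the average effect of each pool over its 4 backgrounds, the interactions, the differences between groups of 1 pool, and the group of all 3 pools against each of those. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, and 0.05 was the threshold. Counts with the slide as a blocking term come from the same model plus the replicate number. For a gene not well above background on any array of 1 group, the lower limit of the fold sets each of those arrays at the lowest signal well above background on it, or at the gene's own signal where that is higher. The 35 gene lists were written by hand before the data were examined and tested when at least 5 members were measured, with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry. Overlap between comparisons that share NT was set against 100 simulated sets of arrays without effects. Their residuals were shuffled over all 24 arrays, without holding the slide fixed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

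The rule for naming genes took, against NT, the targets and the 8 largest rises and 8 largest falls (5 and 5 for groups of 2 pools) among genes that passed, had a symbol and had all 3 siRNA arrays on the same side of the 3 NT arrays. It added up to 4 members with the smallest p of each list described, 8 and 8 genes for average effects, 5 in each direction by p for interactions and differences, and genes reported elsewhere to respond to NR4A receptors. This rule, the groups, the comparisons and most alternatives were chosen before the data were examined.

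The procedure was tested on simulated data with 27831 genes. In siNR4A2 against NT it recovered 47.8%, 77.6% and 90.9% of genes changed by 0.5, 1 and 2 log2 units, with 11 unchanged genes called (7.10% of calls). For the siNR4A2 average it recovered 61.2%, 94.0% and 100% (6 unchanged genes called, 3.41%), and for the interaction of NR4A1 and NR4A2 40.3%, 67.2% and 92.4% (9 unchanged genes called, 6.34%).

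Alternatives were quantile normalisation, median centring, no filter, a filter on all 24 arrays, the mean of a gene's probes, the deposited table, the slide as a block, array weights, a trended robust variance, a minimum change of 1 log2 unit, a fit to the compared arrays alone, rank correlations and leaving out each array. Added after the data were seen were normexp background correction (offset 50) of the median signal, in place of the mean signal that the files do not hold, and leaving out probes with at least 0.5 of their spots within 20 rows or 5 columns of the array border, alone and with the block. The array has 384 rows and 164 columns, and 23469 genes remained without those probes.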

Results

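Messenger RNA was measured in Rh30 cells, an established line of alveolar rhabdomyosarcoma, a childhood tumour with features of unfinished skeletal muscle. The cells were collected 48 h after transfection with pools of short interfering RNAs (siRNAs) against the nuclear receptors NR4A1, NR4A2 and NR4A3, alone and in every combination. Each pool was used at 25 nM, and a non-targeting siRNA (NT) filled each transfection up to 75 nM, so that the NT group received 75 nM of it. The 8 groups, NT, siNR4A1, siNR4A2, siNR4A3, siNR4A1+2, siNR4A1+3, siNR4A2+3 and siNR4A1+2+3, had 3 biological replicates each by their labels. The p-values rest on those labels. The 24 samples were hybridised to 1-colour arrays, and the 75th percentile of the signal ran from 1437 to 1848 intensity units per array. Between 72.7% and 84.3% of the probes were well above background on an array, and 27831 genes were tested. The number of arrays limits the precision.

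The 24 arrays sat on 3 slides, and each slide held the arrays of 1 replicate number, 1 per group. Each group occupied the same place on all 3 slides, with NT and the groups of 1 pool on one side and the groups of several pools on the other, so place and group cannot be separated. Counts are given from a fit by group, followed by the count with the slide as a blocking term. A slide has no replicates within it, so single-slide values carry no test. Fits that leave out 1 array have no slide term and leave 1 group without an array on 1 slide. Slide differences can then enter the change and its spread, so a lost call need not reflect the gene alone. A gene passed when its adjusted p was under 0.05, and the words rose and fell are used for such genes. Changes are log2 values with the standard error (SE). Where no array of a group was well above background for a gene, the fold is a lower limit, computed with that group at the lowest signal well above background on its arrays, and is written as at least N-fold.

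The targeted genes come first. The only NR4A1 probe was not well above background on any of the 24 arrays, NT included, so no fold can be given and the silencing of NR4A1 was not measurable. NR4A2 had 2 probes. The brighter probe, above background on 24 arrays and placed at the edge of the array, gave -0.57 (SE 0.20, adjusted p = 0.0816) in siNR4A2 against NT, 67.3% of control. It passed with the slide as a blocking term (adjusted p = 0.0319) and without siNR4A2 replicate 3 (-0.76, adjusted p = 0.0228), and its values on the slides were -1.08, -0.35 and -0.29. The other NR4A2 probe, inside the array, was above background on 14 arrays: on 3 of 3 in NT, but on only 1 of 3 in each group with siNR4A2, so the fitted changes rest in part on background signal. In the fit it fell by 1.59 (SE 0.44, adjusted p = 0.0297) in siNR4A2, by 1.69 in siNR4A1+2, by 1.53 in siNR4A2+3 and by 1.83 in siNR4A1+2+3. NR4A3 also had 2 probes. The brighter one, above background on all 24 arrays and also at the edge, was at 33.5% of control in siNR4A3 (-1.58, SE 0.36, adjusted p = 0.248; -1.61, -1.79 and -1.33 on the slides), which passed when adjusted over the targets alone (adjusted p = 0.00130). It fell by 1.71 (adjusted p = 0.00415) in siNR4A2+3 and by 1.79 (adjusted p = 0.00249) in siNR4A1+2+3. In siNR4A1+3 it fell by 1.40 (adjusted p = 0.0459), a call that was lost without any 1 of the 6 arrays compared (adjusted p from 0.0806 to 0.151). Its spread was widened by siNR4A1+2, whose scaled signal had an SD of 1.17 against 0.05 in NT, and where the change against NT was 0.51, and -0.16 without replicate 2. The other NR4A3 probe, above background on 17 arrays (2 of 3 in NT and 1 of 3 in siNR4A1+3), gave -0.02 (SE 0.28) in siNR4A3, 0.03 in siNR4A2+3, -0.37 in siNR4A1+3 and -0.35 in siNR4A1+2+3, and passed in none of these. In siNR4A1, neither NR4A2 (-0.19, SE 0.20) nor NR4A3 (-0.03, SE 0.36) passed. The brighter NR4A2 probe fell by 0.65 (adjusted p = 0.0402) in siNR4A1+2+3 and did not pass there without NT replicate 1 (0.139), NT replicate 3 (0.125), siNR4A1+2+3 replicate 2 (0.160) or siNR4A1+2+3 replicate 3 (0.0895).

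**Figure D1:**
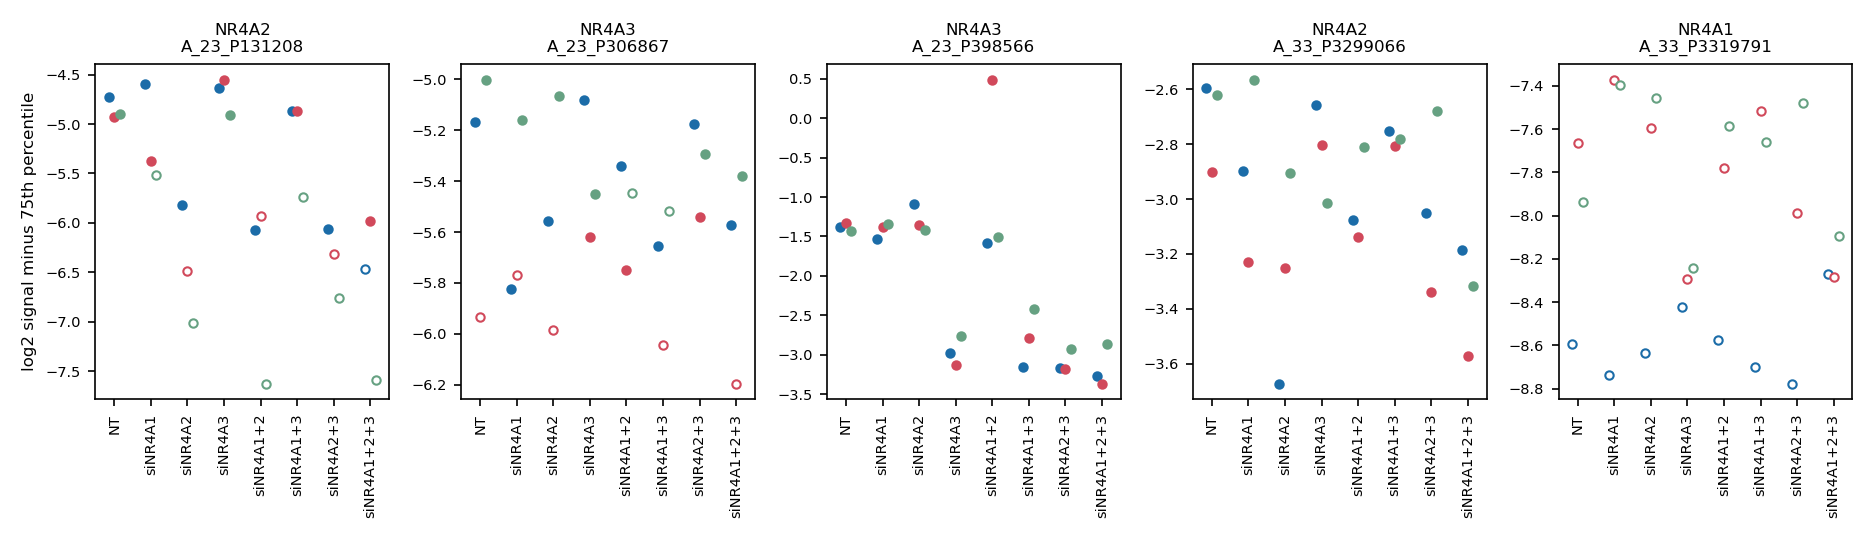
Signal of each NR4A probe on each of the 24 arrays (log2 after subtracting the 75th percentile of the array), by group and replicate. Filled points are well above background and open points are not; the NR4A1 probe is open on all arrays.

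The siNR4A1 group was compared with NT to ask which transcripts change with the siNR4A1 pool alone. ANGPTL4, which encodes a secreted inhibitor of lipoprotein lipase, rose the most, and NPPB, the natriuretic peptide of stretched muscle, rose with it. The pentose phosphate enzyme TKT, the kinase anchor AKAP7 and the cytokine IL11 fell. The growth factor targets ETV4, DUSP6 and SPRY4 fell as well. Of 27831 genes, 120 passed, 65 up and 55 down, and 178 passed with the slide term. In fits without 1 array, and without the slide term, the count was lower each time. It was 40, 49 and 50 without NT replicates 1, 2 and 3. It was 49, 62 and 29 without siNR4A1 replicates 1, 2 and 3. Of the 120 genes, ANGPTL4 alone changed by over 1 log2 unit (1.05, SE 0.17, adjusted p = 0.00763), with 1.51, 0.76 and 0.88 on the slides. It did not pass without NT replicate 1 (0.91, adjusted p = 0.0600), siNR4A1 replicate 1 (0.96, 0.0556) or siNR4A1 replicate 3 (1.03, 0.0572). PGM2L1 rose by 0.61, ZNF76 by 0.60, NPPB by 0.57, STRADB by 0.53, SLC25A34 by 0.52 and ANKRD2 by 0.52 (SE 0.05 to 0.09). The complement factor gene CFI, above background on 1 of 3 arrays in either group, had 0.74 (adjusted p = 0.0262) and passed in only 1 of the 6 fits that leave out 1 array, that without NT replicate 2; the others gave 0.121 and 0.164 (NT replicates 1 and 3) and 0.114, 0.0745 and 0.114 (siNR4A1 replicates 1, 2 and 3). TKT fell by 0.91 (SE 0.05, adjusted p = 3.26e-08; -0.87, -0.92 and -0.93 on the slides). MFAP4 fell by 0.85, CTDSPL by 0.82, AKAP7 by 0.79, OLFM1 by 0.74, IL11 by 0.71 and CBX6 by 0.65 (SE 0.08 to 0.10), while a further OLFM1 probe gave -0.35 and did not pass. ETV4 fell by 0.55 (SE 0.11, adjusted p = 0.0368) and lost its call without any 1 of the 6 arrays (0.114 to 0.177).

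Among the 35 gene lists, the 39 early genes of growth factor signalling shifted down in siNR4A1 (4 fell, 0 rose, 35 did not pass; 7 fell when adjusted over the list alone; median -0.04). Its camera test gave an adjusted p of 0.000442, and adjusted p = 0.248 with an estimated correlation. SPRY4 (-0.50 on an edge probe), ETV5 (-0.31), ETV4 and DUSP6 (-0.42) were the members that fell. SPRY4 and ETV5 lost their calls without any 1 of the 6 arrays (adjusted p 0.0513 to 0.0856 and 0.0832 to 0.187). DUSP6 lost its call without NT replicate 2 (0.109), NT replicate 3 (0.104), siNR4A1 replicate 1 (0.115) and replicate 3 (0.0718). No list passed with both correlations in siNR4A1.

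For the siNR4A2 pool the question was the same. The small heat shock protein of muscle HSPB3, the X-linked muscle protein SMPX, the myosin methyltransferase SMYD1, the leiomodin LMOD3 and the atrophy ligase FBXO32 were 5 of the 8 largest rises of genes with a symbol, and SSX4B, SLC44A3 and the tight junction gene CLDN5 were the others. The cargo receptor LMAN2, the disulfide isomerase TXNDC5, the growth factor target ETV4 and the cyclin CCND3 fell. In all 2505 genes passed, 1547 up and 958 down, and 3636 with the slide term; 1514 passed without NT replicate 1. Scaling by the median of each array gave 1457 rises among 1914 genes (76.1% in place of 61.8%). HSPB3 rose by 2.09 (SE 0.08, adjusted p = 5.35e-11), SMPX by 1.86 (SE 0.11), SSX4B by 1.77 (SE 0.11), SLC44A3 by 1.70 (SE 0.14) and CLDN5 by 1.67 (SE 0.10). SMYD1 rose by 1.61 (SE 0.11), LMOD3 by 1.51 (SE 0.16) and FBXO32 by 1.45 (SE 0.15). TPPP fell by 1.29 (SE 0.14), LMAN2 by 1.27 (SE 0.06, adjusted p = 2.78e-10), GLCE by 1.16 (SE 0.12), NETO2 by 1.13 (SE 0.07), ETV4 by 1.13 (SE 0.11) and CCND3 by 1.02 (SE 0.11). TXNDC5 fell by 1.25 (SE 0.10) on 1 probe and by 0.27 on the other. SPATA6 fell by 1.14 (SE 0.34, adjusted p = 0.0396), with -2.28, -0.93 and -0.22 on the slides; it did not pass without NT replicate 1 (-0.63, 0.231), siNR4A2 replicate 1 (-1.09, 0.123) or siNR4A2 replicate 2 (-0.99, 0.124).

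Of the 46 muscle differentiation genes, 28 rose in siNR4A2, 0 fell and 18 did not pass (34 rose when adjusted over the list alone). The median was 0.42 (0.47, 0.44 and 0.37 on the slides), with a camera adjusted p of 1.87e-32 and adjusted p = 0.000283 with an estimated correlation. TNNC1 (1.06), MYBPH (1.33), MYL1 (0.82) and KLHL41 (1.24) had the smallest p-values. Of 11 genes reported to rise when NR4A receptors are silenced, 6 rose, 0 fell and 5 did not pass (7 rose when adjusted over the list alone; camera adjusted p = 1.08e-06, and adjusted p = 0.0456 with an estimated correlation). Autophagy and lysosome genes shifted up (9 rose, 1 fell and 33 did not pass of 43; 14 rose and 1 fell when adjusted over the list alone), with camera adjusted p = 1.02e-05 and adjusted p = 0.0456 with an estimated correlation. NEU1 (1.03), GABARAPL1 (0.47) and NPC1 (0.32) rose in it and ATP6V1A (-0.33) fell. Histone genes fell in 9 of 36 cases, with 0 rises and 27 not passing (16 fell when adjusted over the list alone; median -0.37); the camera adjusted p was 1.18e-09, and adjusted p = 0.408 with an estimated correlation. H2AC13 fell by 0.97 and H3C10 by 0.68.

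**Figure D2:**
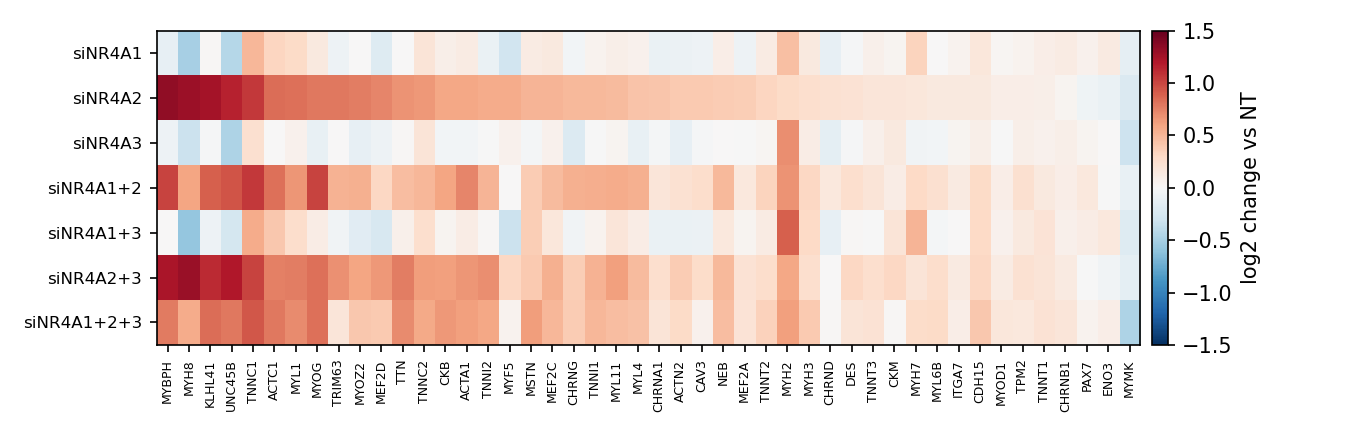
Change against NT (log2, colour) of the 46 muscle differentiation genes in the 7 siRNA groups, sorted by the change in siNR4A2. The list's median is 0.42 in siNR4A2, 0.36 in siNR4A1+2, 0.39 in siNR4A2+3, 0.39 in siNR4A1+2+3, 0.05 in siNR4A1 and 0.07 in siNR4A1+3.

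The siNR4A3 group showed few changes. NPPB rose, and the Hippo pathway kinase STK3, the translation repressor EIF4EBP2, the galactosyltransferase B4GALT3 and the ATP synthase subunit ATP5F1C fell. limma passed these 5 genes, 1 up and 4 down, 14 with the slide term, and 1461 genes had an unadjusted p under 0.05. Other scalings gave 4 rises of 9 genes (quantile normalisation and the deposited table) and 2 of 5 (median centring). STK3 changed by -0.66 (SE 0.07, adjusted p = 0.000454), ATP5F1C by -0.56 (SE 0.07), EIF4EBP2 by -0.54 (SE 0.06) and B4GALT3 by -0.50 (SE 0.06); further probes of EIF4EBP2 and B4GALT3 gave -0.55 and -0.50. NPPB had 0.51 (SE 0.07, adjusted p = 0.00781) and did not pass without NT replicate 2 (0.0846), NT replicate 3 (0.0835), siNR4A3 replicate 2 (0.104) or siNR4A3 replicate 3 (0.0911). Interferon response genes shifted up by a median of 0.08 (camera adjusted p = 6.28e-07, and adjusted p = 0.0191 with an estimated correlation), although 0 of 41 passed over all genes (3 rose when adjusted over the list alone).

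The siNR4A1+2 group addressed the joint effect of the siNR4A1 and siNR4A2 pools. In it 26 of the 46 muscle differentiation genes rose, and 11 of the 39 early genes of growth factor signalling fell. HSPB3, CLDN5 and the titin-binding ANKRD2 rose, and TPPP, GLCE and TXNDC5 fell, but some probes at the edge of the array moved by more. In total 1945 genes passed, 1009 up and 936 down (2471 with the slide term). HSPB3 rose by 1.74 (SE 0.08), SSX4B by 1.72 (SE 0.11), CLDN5 by 1.69 (SE 0.10) and ANKRD2 by 1.50 (SE 0.05, adjusted p = 1.12e-11). TPPP fell by 1.50 (SE 0.14), GLCE by 1.44 (SE 0.12), TXNDC5 by 1.38 (SE 0.10), and ZNF215 was at least 3.21-fold lower (adjusted p = 0.00351). SPICE1, above background on 3 arrays of siNR4A1+2 and 1 of NT, had 1.65 (SE 0.45, adjusted p = 0.0311) and passed in only 1 fit without 1 array, that without siNR4A1+2 replicate 2; without NT replicates 1, 2 and 3 the adjusted p was 0.0757, 0.0719 and 0.116, and without siNR4A1+2 replicates 1 and 3 it was 0.0973 and 0.134. TRAF3IP3 was at least 3.04-fold lower (adjusted p = 0.0406), which was lost without NT replicate 1 (0.206), NT replicate 2 (0.123), siNR4A1+2 replicate 2 (0.216) or replicate 3 (0.0694). Muscle differentiation genes rose in 26 cases, fell in 0 and did not pass in 20 (31 rose when adjusted over the list alone; camera adjusted p = 1.37e-32, and adjusted p = 0.000276 with an estimated correlation). Of the early growth factor genes, 11 fell, 0 rose and 28 did not pass (13 fell when adjusted over the list alone; camera adjusted p = 4.45e-08, and adjusted p = 0.0226 with an estimated correlation), among them ETV4 (-1.33), ETV5 (-0.75), SPRY4 (-0.70 on an edge probe, 0.088 on the other) and DUSP6 (-0.68).

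The siNR4A1+3 group asked for the joint effect of the siNR4A1 and siNR4A3 pools. ANGPTL4 and PGM2L1 rose and AKAP7 and TKT fell, as in siNR4A1. The immediate early transcription factor EGR1 was lower. Of the tested genes 621 passed, 507 up and 114 down (990 with the slide term), and the count was 265, 404 and 245 without NT replicates 1, 2 and 3 and 197 without siNR4A1+3 replicate 3. ANGPTL4 rose by 1.15 (SE 0.17), PGM2L1 by 0.93 (SE 0.09, adjusted p = 1.06e-05) and CFI by 0.89 (SE 0.14; 3 of 3 arrays above background against 1 of 3 in NT). AKAP7 fell by 0.88 (SE 0.08) and TKT by 0.85 (SE 0.05, adjusted p = 9.15e-08). EGR1 fell by 0.97 (SE 0.21, adjusted p = 0.0169) and did not pass without NT replicate 1 (-0.83, 0.106), NT replicate 2 (-0.93, 0.0616) or siNR4A1+3 replicate 3 (-0.85, 0.111). Dim probes at the array edge gave SMC1B at least 2.60-fold higher (0.0566 without siNR4A1+3 replicate 3) and ZNF215 at least 2.62-fold lower (0.0827 without NT replicate 3 and 0.0628 without siNR4A1+3 replicate 3). TEX44 was at least 2.62-fold higher (adjusted p = 0.0431), and passed only without NT replicate 1; the adjusted p was 0.137 and 0.209 without NT replicates 2 and 3, and 0.0813, 0.105 and 0.165 without siNR4A1+3 replicates 1, 2 and 3. Early growth factor genes fell in 5 cases, rose in 0 and did not pass in 34 (7 fell when adjusted over the list alone; median -0.11; camera adjusted p = 2.17e-09, and adjusted p = 0.0204 with an estimated correlation). Muscle differentiation genes rose in 6 cases, with 0 falls and 40 not passing (8 rose when adjusted over the list alone), with a camera adjusted p of 0.0215 and adjusted p = 0.522 with an estimated correlation. That call was lost without NT replicate 1 (0.0515), NT replicate 3 (0.131) or siNR4A1+3 replicate 1 (0.0933).

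In siNR4A2+3, which joined the siNR4A2 and siNR4A3 pools, the muscle genes HSPB3, SMPX, SMYD1 and APOBEC2 rose and TPPP and LMAN2 fell. The sperm fibre protein ROPN1 also rose, on a probe at the edge of the array. A total of 2389 genes passed, 1572 up and 817 down (3075 with the slide term). ROPN1 rose by 3.27 (SE 0.39, adjusted p = 1.98e-05; 2 of 3 NT arrays above background), LINC00700 was at least 4.26-fold higher and CFAP144 at least 5.10-fold higher, all from edge probes. The fitted change of CFAP144 was 3.12, and 2.01 without siNR4A2+3 replicate 3. PCDHAC1 was at least 6.84-fold higher (adjusted p = 0.0498), which was lost without NT replicates 1, 2 or 3 (0.0927, 0.0936, 0.179) and siNR4A2+3 replicates 2 or 3 (0.193, 0.239). ZMAT1, above background on 1 of 3 NT arrays, had 2.03 (SE 0.56, adjusted p = 0.0278), lost without NT replicate 2 (0.0683), NT replicate 3 (0.15) or siNR4A2+3 replicate 3 (0.182). Away from the edge, for genes chosen after their values were seen, HSPB3 rose by 2.02 (SE 0.08, adjusted p = 5.15e-11), CLDN5 by 1.75 (SE 0.10), SMPX by 1.69 (SE 0.11), SMYD1 by 1.58 (SE 0.11) and APOBEC2 by 1.47 (SE 0.11). TPPP fell by 1.53 (SE 0.14) and LMAN2 by 1.40 (SE 0.06). On edge probes, ZNF215 was at least 2.37-fold lower (adjusted p = 0.00617), and TRAF3IP3 was at least 2.48-fold lower (adjusted p = 0.0438) and passed only without NT replicate 3; the adjusted p was 0.223 and 0.119 without NT replicates 1 and 2, and 0.0626, 0.199 and 0.0618 without siNR4A2+3 replicates 1, 2 and 3. Muscle differentiation genes rose in 29 cases, with 0 falls and 17 not passing (34 rose when adjusted over the list alone; camera adjusted p = 1.59e-31, and adjusted p = 0.000336 with an estimated correlation).

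The siNR4A1+2+3 group asked what the 3 pools do together. In it CLDN5 and the muscle genes ANKRD2 and HSPB3 rose, and ETV4, TPPP, LMAN2 and TXNDC5 fell. Targets of PAX3-FOXO1, the fusion protein that drives this tumour, also shifted up. Any genes that this list shares with the muscle differentiation list were kept in it throughout, so both shifts need not be independent. The test passed 2823 genes, 1890 up and 933 down (3874 with the slide term). CLDN5 rose by 1.58 (SE 0.10), ANKRD2 by 1.58 (SE 0.05, adjusted p = 4.35e-12), SSX4B by 1.54 (SE 0.11), HSPB3 by 1.51 (SE 0.08) and CFI by 1.47 (SE 0.14). ETV4 fell by 1.57 (SE 0.11, adjusted p = 3.94e-08), TPPP by 1.49 (SE 0.14), LMAN2 by 1.28 (SE 0.06), TXNDC5 by 1.24 (SE 0.10) and GLCE by 1.17 (SE 0.12). Among dim probes, MLC1 was at least 2.63-fold higher (adjusted p = 0.000134) and ZNF215 at least 3.24-fold lower (adjusted p = 0.00106). LINC00700 was at least 3.31-fold higher (adjusted p = 0.0108; 0.0570 without NT replicate 1). SMC1B was at least 1.57-fold higher (adjusted p = 0.0246), lost without NT replicate 1 (0.0901), NT replicate 3 (0.0725), or siNR4A1+2+3 replicates 2 (0.128) and 3 (0.117). EPN3 was at least 2.41-fold lower (adjusted p = 0.0258), lost without NT replicate 2 (0.0945), NT replicate 3 (0.0893), or siNR4A1+2+3 replicates 1 (0.125) and 2 (0.0691).

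Of the muscle differentiation genes, 25 rose in siNR4A1+2+3, 0 fell and 21 did not pass (31 rose and 1 fell when adjusted over the list alone; camera adjusted p = 7.7e-24, and adjusted p = 0.00163 with an estimated correlation). Early growth factor genes gave 11 falls, 1 rise and 27 not passing (15 falls and 1 rise when adjusted over the list alone; camera adjusted p = 1.52e-07, and adjusted p = 0.0300 with an estimated correlation). FOSL1 fell by 0.82 and SPRY4 by 0.88, both on edge probes, and ETV5 fell by 0.68. PAX3-FOXO1 targets gave 16 rises, 0 falls and 21 not passing of 37 (20 rises and 2 falls when adjusted over the list alone; camera adjusted p = 3.94e-07, and adjusted p = 0.0449 with an estimated correlation).

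**Figure D3:**
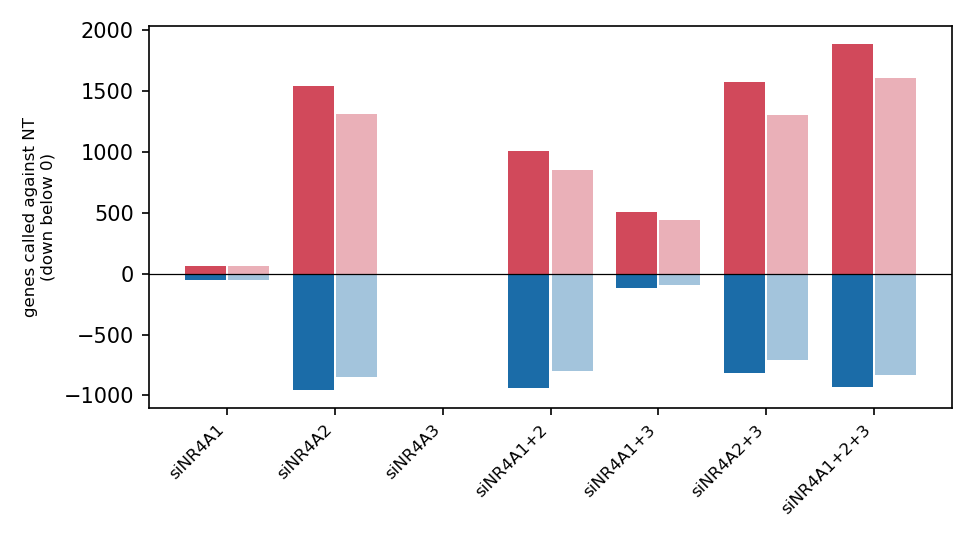
Genes that passed (count, rises above 0 and falls below 0) in each siRNA group against NT. Dark bars use all genes and pale bars leave out the probes at the array edge; siNR4A2 had 1547 rises and 958 falls over all genes.

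Probes at the edge of the array weigh on the largest changes in the groups of several pools, but not on the passing genes as a whole. Such probes made up 18.4% of the genes tested. Among all passing genes they made up 18.7% in siNR4A1+2, 18.4% in siNR4A1+3, 18.8% in siNR4A2+3 and 17.4% in siNR4A1+2+3. Among passing genes that changed by over 1 log2 unit they made up 77.8% in siNR4A1+3 (7 of 9) and 41.3% in siNR4A2+3 (38 of 92). The share was 32.8% in siNR4A1+2 (22 of 67) and 32.6% in siNR4A1+2+3 (28 of 86), against 18.5% in siNR4A2 (12 of 65). Without them 114, 2162, 4, 1647, 541, 2011 and 2441 genes passed in siNR4A1, siNR4A2, siNR4A3, siNR4A1+2, siNR4A1+3, siNR4A2+3 and siNR4A1+2+3. Over all genes, the 3 arrays of a group and the 3 of NT did not overlap for 13.1% of genes in siNR4A1, 22.6% in siNR4A2, 14.0% in siNR4A3 and 27.8% in siNR4A1+2+3, where chance gives 10%. Among genes over 1 log2 unit in the average effects, edge probes were 12 of 12 for siNR4A3, 2 of 2 for siNR4A1 and 13 of 51 for siNR4A2. Besides NR4A2 and NR4A3, the named genes read at the edge were ANKRD2, ATP6V0A4, BMP5, CFAP144, CHORDC1, DKK1, FOSL1, FOXB2, ICOSLG, IDH1, KRT79, LDB2, LINC00602, LINC00700, LMOD3, LRRIQ1, MLC1, MYH7, MYL1, MYOG, NEU1, OR5I1, PCDHAC1, POLA1, PRAC1, PSKH1, ROPN1, SMC1B, SMIM13, SPICE1, SPRY4, SSX4B, STK3, TEX44, TKT, TRAF3IP3, ZMAT1 and ZNF215.

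**Figure D4:**
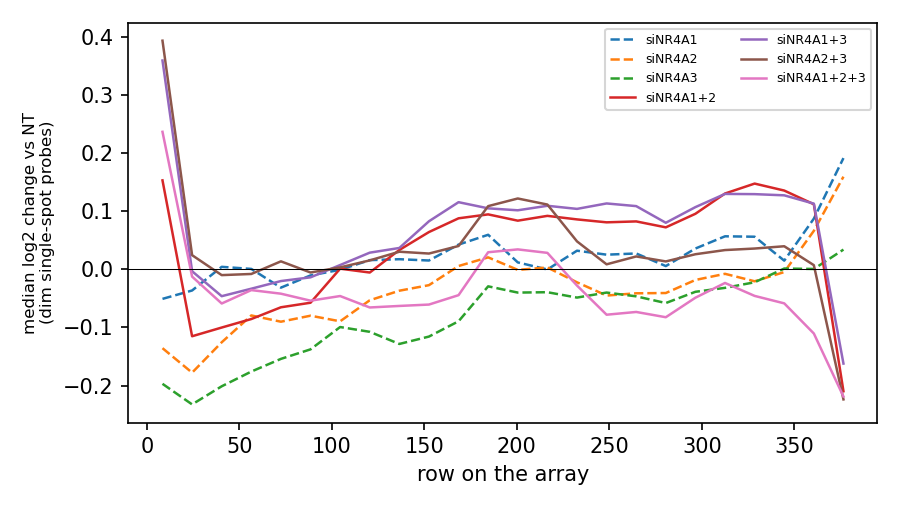
Median change against NT (log2) of dim probes with 1 spot, by row of the array in 24 bins, for the 7 siRNA groups. Dashed lines are groups on the side of the slide with NT and solid lines those on the other side, where top minus bottom rows ran from 0.24 to 0.49.

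The average effect of a pool compares the 12 arrays that received it with the 12 that did not, within each background of the other pools. More of the arrays with a pool than of those without it lay on the side of the groups of several pools. The side of the slide is therefore mixed into each average. For siNR4A1, TKT, AKAP7, IL11 and the integrin ITGB1 fell, and PGM2L1, the signalling adaptor SHC3 and ANKRD2 rose. The average passed 1503 genes, 892 up and 611 down (2158 with the slide term), and median centring gave 333 rises of 758 (43.9% in place of 59.3%). SHC3 rose by 0.66 (SE 0.13), ANKRD2 by 0.63 (SE 0.03, adjusted p = 1.17e-10), PGM2L1 by 0.52, ANGPTL4 by 0.49, ZNF76 by 0.48, KCNF1 by 0.47 and STRADB by 0.39. ARSJ fell by 0.80 (SE 0.11), TKT by 0.78 (SE 0.03, adjusted p = 2.75e-12), AKAP7 by 0.77 (SE 0.04), FBXL16 by 0.63 (SE 0.13), ARMC1 by 0.62 (SE 0.07) and IL11 by 0.59 (SE 0.04). DNAAF2 fell by 0.68 on 1 probe and gave 0.00 on the other. SMC1B and ZNF215 also passed but were not well above background on most arrays of 1 side, and ZNF215 lost its call without NT replicate 3 (0.0502), siNR4A1 replicate 1 (0.0513) or siNR4A1+2+3 replicate 2 (0.0509).

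Early growth factor genes fell in 13 cases on average with siNR4A1, with 0 rises and 26 not passing (17 falls and 1 rise when adjusted over the list alone; median -0.08; camera adjusted p = 2.03e-16, and adjusted p = 0.00128 with an estimated correlation). SPRY4 (-0.44 on an edge probe), DUSP6 (-0.34), KLF2 (-0.29) and ETV5 (-0.29) had the smallest p-values. Integrin and adhesion genes gave 5 falls, 3 rises and 19 not passing of 27 (6 falls and 3 rises when adjusted over the list alone; camera adjusted p = 0.000900, and adjusted p = 0.0122 with an estimated correlation), and ITGB1 fell by 0.41 (SE 0.06, adjusted p = 0.000393). Genes reported to fall when NR4A receptors are silenced gave 5 falls, 3 rises and 13 not passing of 21 (11 falls and 3 rises when adjusted over the list alone; camera adjusted p = 0.000641, and adjusted p = 0.0122 with an estimated correlation). IDH1, reported to depend on NR4A1, rose by 0.34 (SE 0.03, adjusted p = 1.06e-06). BIRC5 did not pass in siNR4A1 against NT (0.00).

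For siNR4A2, 36 of the 46 muscle differentiation genes rose on average. HSPB3, CLDN5 and SMPX rose, and TPPP, LMAN2 and the adaptor SHC4 fell. The cell cycle inhibitor CDKN1A rose, and ETV4 and the receptor gene EGFR (on 1 of its probes) fell. A total of 5948 genes passed, 3008 up and 2940 down (6980 with the slide term). HSPB3 rose by 1.72 (SE 0.04, adjusted p = 2.82e-15), CLDN5 by 1.57 (SE 0.05), SLC44A3 by 1.49 (SE 0.07), ATP6V0A4 by 1.44 (SE 0.05), SSX4B by 1.43 (SE 0.06) and SMPX by 1.43 (SE 0.05). LRRIQ1 and LINC00700 passed but were not well above background on most arrays of 1 side. TPPP fell by 1.48 (SE 0.07), LMAN2 by 1.34 (SE 0.03, adjusted p = 9.33e-16), SHC4 by 1.26 (SE 0.05), TXNDC5 by 1.18 (SE 0.05), GLCE by 1.17 (SE 0.06), NETO2 by 1.11 (SE 0.03) and ETV4 by 1.03 (SE 0.06). FERMT2 fell by 1.08 (SE 0.06) on 1 probe and by 0.40 on another. CDKN1A rose by 0.54 (SE 0.07, adjusted p = 5.72e-06) and GDF15 by 0.42. BIRC5 fell by 0.19 (adjusted p = 0.000247), and EGFR by 0.27 (SE 0.03) on 1 of its 3 probes, with -0.10 and 0.03 on the others.

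The muscle differentiation list gave 36 rises, 1 fall and 9 not passing with the siNR4A2 average (38 rises and 1 fall when adjusted over the list alone; median 0.38; camera adjusted p = 8.26e-30, and adjusted p = 0.000466 with an estimated correlation), with MYBPH at 1.14, KLHL41 at 1.05, TNNC1 at 0.69 and MYL1 at 0.59. PAX3-FOXO1 targets gave 18 rises, 2 falls and 17 not passing (22 rises and 4 falls when adjusted over the list alone; camera adjusted p = 1.18e-07, and adjusted p = 0.0471 with an estimated correlation), with MYOG at 0.83, BMP5 at 0.61, CXCR4 at 0.51 and TNNI1 at 0.48. DNA replication genes gave 26 falls, 4 rises and 18 not passing of 48 (29 falls and 7 rises when adjusted over the list alone; camera adjusted p = 5.33e-06, and adjusted p = 0.400 with an estimated correlation). GINS3 fell by 0.48, DTL by 0.36, POLA1 by 0.36 and MCM3 by 0.35. Mitosis genes gave 19 falls, 4 rises and 18 not passing of 41 (22 falls and 4 rises when adjusted over the list alone; camera adjusted p = 1.24e-05, and adjusted p = 0.400 with an estimated correlation).

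For siNR4A3 the average effect had its own target, NR4A3, at -1.76 (SE 0.18, adjusted p = 4.04e-05) on the edge probe, and at -0.04 (SE 0.14, adjusted p = 0.95) on the probe inside the array. All 12 genes over 1 log2 unit in this average were read at the edge. STK3 fell by 0.58 (SE 0.04, adjusted p = 1.07e-07), B4GALT3 by 0.43 (SE 0.03) and ATP5F1C by 0.39 (SE 0.04). The kinase PSKH1 rose by 0.42 (SE 0.04, adjusted p = 6.65e-06), and the chaperone CHORDC1 rose by 0.41 (SE 0.05) on 1 probe and 0.12 on the other. CDKN1A fell by 0.37 (adjusted p = 0.00892). The average passed 447 genes, 370 up and 77 down (1002 with the slide term), and normexp background correction gave 268 rises of 452 (59.3% in place of 82.8%). The count was 268 and 279 without NT replicates 1 and 3, 277 without siNR4A1 replicate 3, 1102 without siNR4A2 replicate 1, 234 without siNR4A3 replicate 2, and 250 and 293 without siNR4A1+2 replicates 1 and 3. It was 281 without siNR4A1+3 replicate 3, 279 and 251 without siNR4A2+3 replicates 2 and 3, and 285 without siNR4A1+2+3 replicate 3. LDB2 (-0.96 on 1 probe, 0.07 on the other) lost its call in 17 of the 24 fits that leave out 1 array and DRC8 (0.39, SE 0.09) in 14. LINC00700, PRAC1, OR5I1, ICOSLG, FOXB2, LINC00602, ZNF215 and KRT79 passed from dim probes, not well above background on most arrays of 1 side. Among these, calls were lost on leaving out 1 array in 19 of 24 fits for OR5I1 and LINC00602, 18 for LINC00700 and KRT79, 16 for FOXB2 and 3 for ICOSLG. No list passed with both correlations for the siNR4A3 average.

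Changes with a pool were correlated across genes between its 4 backgrounds, which share no array; genes are not independent replicates. The mean r over 6 pairs was 0.30 (SD 0.13) for siNR4A2, 0.12 (SD 0.23) for siNR4A3 and 0.04 (SD 0.21) for siNR4A1. For the pair of backgrounds in which each comparison stays on 1 side of the slide, r was 0.44 for siNR4A2, 0.29 for siNR4A3 and 0.19 for siNR4A1. For the pair in which each comparison crosses the sides, it was 0.48, 0.48 and 0.39. Without edge probes, in the same order of pools, the mean r was 0.39, 0.090 and 0.10, that within sides 0.48, 0.30 and 0.21, and that across sides 0.45, 0.20 and 0.28. Added to siNR4A1, siNR4A3 or both, the siNR4A2 pool passed 1813, 2139 and 1647 genes (2531, 2912 and 2232 with the slide term), and 22 of the 46 muscle differentiation genes rose in all 4 backgrounds. The siNR4A1 pool passed 110, 102 and 93 genes when added to siNR4A2, siNR4A3 or both (310, 189 and 135 with the slide term). The siNR4A3 pool passed 5, 2 and 25 when added to siNR4A1, siNR4A2 or both (8, 5 and 112 with the slide term), and 9, 0 and 21 without edge probes.

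Interactions ask whether the effects of 2 pools add up. For NR4A1 and NR4A2, 3 muscle genes changed by less than the sum of both pools: the troponin TNNC1, the myosin light chain MYL1 and HSPB3. limma passed 6 genes, all below 0 (8 with the slide term), with 1048 at an unadjusted p under 0.05. TNNC1 had -0.45 (SE 0.05, adjusted p = 0.00235), a call kept in every fit without 1 array. The others were MYL1 (-0.36, SE 0.05), HSPB3 (-0.53, SE 0.08), CR601050 (-0.61, SE 0.10), ENST00000431042 (-0.47, SE 0.07) and VAC14-AS1 (-0.47, SE 0.08; -0.06 on its other probe). VAC14-AS1, the last of the 6, was named after its values were seen. In the 24 fits that leave out 1 array, MYL1 lost its call in 17, HSPB3 in 19, CR601050 in 21, ENST00000431042 in 16 and VAC14-AS1 in 21. Without any 1 array other than NT replicate 2 and the siNR4A2 arrays, the count was between 1 and 3. For NR4A2 and NR4A3, NPPB (-0.51, SE 0.07) and PKP3 (-0.40, SE 0.06) passed, both with adjusted p = 0.0320 (5 genes with the slide term; 834 at an unadjusted p under 0.05). NPPB lost its call in 17 of the 24 fits and PKP3 in 21. The count was 0 under quantile normalisation, median centring, normexp, no filter on dim probes and in the deposited table, and 1 with a trended robust variance. It was also 0 or 1 without any 1 array other than NT replicate 1, siNR4A1 replicate 1 and siNR4A2+3 replicate 1. For NR4A1 and NR4A3 limma passed 0 genes, and 444 had an unadjusted p under 0.05. The interaction of all 3 passed 0 genes (20 with the slide term, 0 with the slide term and without edge probes; 2154 at an unadjusted p under 0.05), with 1 gene without NT replicate 3, siNR4A1+2 replicate 1 or siNR4A1+2+3 replicate 1, 2 without siNR4A2+3 replicate 1, and 6 and 5 without siNR4A2 replicates 1 and 3.

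Direct differences between the groups of 1 pool tested whether the pools' effects are distinct. Against siNR4A2, siNR4A1 had more LMAN2 (1.28, SE 0.06, adjusted p = 2.28e-10), NETO2 (1.11), LOXL4 (0.93), DDOST (0.89) and CIAO2A (0.74), and less HSPB3 (-1.93, SE 0.08), SRL (-1.64), RNF186 (-1.21), SLC45A3 (-1.11) and ESYT3 (-1.08). This difference passed 3136 genes, 1515 up and 1621 down (4008 with the slide term), 1913 without siNR4A1 replicate 1, and median centring gave 816 higher of 2255 (36.2% in place of 48.3%). Against siNR4A3, siNR4A1 had more B4GALT3 (0.63, SE 0.06), STK3 (0.63), ATP5F1C (0.53), ANKRD2 (0.43) and CREBL2 (0.43), and less TKT (-0.92, SE 0.05, adjusted p = 2.5e-08), AKAP7 (-0.69), EPDR1 (-0.56), PRKACA (-0.54) and HAS2 (-0.49). Here 90 genes passed, 36 up and 54 down (124 with the slide term), with 41, 44 and 42 without siNR4A1 replicates 1, 2 and 3 and 47, 36 and 38 without siNR4A3 replicates 1, 2 and 3. Median centring gave 8 higher of 38 (21.1% in place of 40%) and normexp 17 of 57 (29.8%). Against siNR4A3, siNR4A2 had more HSPB3 (1.95, SE 0.08), VAC14-AS1 (1.47; 0.29 on its other probe), ESYT3 (1.22, SE 0.05), RNF186 (1.16) and SLC45A3 (1.00), and less LMAN2 (-1.30, SE 0.06), NETO2 (-1.14), DDOST (-0.88), KLHL12 (-0.86; -0.28 on its other probe) and CIAO2A (-0.76). That difference passed 2300 genes, 1181 up and 1119 down (3002 with the slide term).

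The siNR4A1+2+3 group was also set against each group of 1 pool, to ask what the other pools add. Over siNR4A1 it had more ESYT3 (1.21, SE 0.05), RNF186 (1.22), ANKRD2 (1.07), SLC45A3 (0.99) and NEU1 (0.95), and less LMAN2 (-1.29), NETO2 (-1.08), LOXL4 (-0.92), DDOST (-0.83) and CIAO2A (-0.77). This passed 2064 genes, 1257 up and 807 down (2754 with the slide term; 1337 without siNR4A1 replicate 1). Over siNR4A2 it had more SYNDIG1 (0.95), PSKH1 (0.85), ANKRD2 (0.79, SE 0.05, adjusted p = 2.94e-07), SMIM13 (0.69) and NCEH1 (0.62), and less IL11 (-0.82), HAS2 (-0.76), CLDN4 (-0.71, SE 0.05), DKK1 (-0.65) and TKT (-0.62). Here 667 genes passed, 423 up and 244 down (1111 with the slide term), with 425 without siNR4A2 replicate 1 and 340, 364 and 332 without siNR4A1+2+3 replicates 1, 2 and 3. Over siNR4A3 it had more ANKRD2 (1.50, SE 0.05, adjusted p = 1.1e-11), ESYT3 (1.34), SNAI1 (1.25), RNF186 (1.17) and BMF (1.15), and less LMAN2 (-1.31), NETO2 (-1.11), HBEGF (-1.08), DDOST (-0.82) and CIAO2A (-0.80). In this comparison 2021 genes passed, 1209 up and 812 down (2546 with the slide term).

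Whether the pools share targets was examined across genes. All changes against NT share the NT arrays, which alone produces a correlation, and 3 arrays cannot be split between comparisons. The value from simulated arrays without any effect is given beside each r. The simulation did not hold the slide fixed, whereas each real group had 1 array per slide. Slide differences therefore enter the simulated changes but balance out in the real ones. A real value below the simulated one thus cannot argue against shared effects. For siNR4A1 and siNR4A2 r was 0.41 (simulated 0.47; covariance 0.0175 against 0.0249), with 31 genes up in both, 14 down in both and 20 opposite. Independent calls would give 3.61 and 1.89, and the simulated arrays gave a mean of 0.77 and 12.9. For siNR4A1 and siNR4A3 r was 0.48 (simulated 0.44; covariance 0.0156 against 0.0214), and NPPB was the 1 shared gene. For siNR4A2 and siNR4A3 r was 0.46 (simulated 0.42; covariance 0.0211 against 0.0206), with 0 shared genes and 1 opposite. For siNR4A2 and siNR4A1+2+3 r was 0.60 (simulated 0.46; covariance 0.0384 against 0.0233), with 991 genes up in both, 487 down in both and 4 opposite, where independent calls would give 105 and 32.1. For siNR4A1 and siNR4A1+2+3 r was 0.38 (simulated 0.50; covariance 0.0172 against 0.0248), with 50 up in both, 34 down in both and 5 opposite against 4.41 and 1.84. For siNR4A3 and siNR4A1+2+3 r was 0.46 (simulated 0.47; covariance 0.0225 against 0.0233), with 3 down in both and 1 opposite. The simulated arrays gave a mean of 0 genes up and 0 down in both for siNR4A2 with siNR4A1+2+3. They gave the same for siNR4A1 with siNR4A1+2+3. The simulated arrays carry no effects, so these counts of 0 do not show how many real calls the shared controls add. Part of any excess may still come from the shared controls. No gene passed in all 3 groups of 1 pool in the same direction. In each pair of comparisons that share no array, 1 stayed on 1 side of the slide and the other crossed the sides. Such pairs of the same pool gave r from -0.17 to 0.06 for siNR4A1. They gave 0.15 to 0.27 for siNR4A2 and -0.16 to 0.06 for siNR4A3. A low or negative r between pools therefore cannot decide whether they share targets. Between pools the mean r was -0.12 for siNR4A1 and siNR4A2, -0.20 for siNR4A1 and siNR4A3 and -0.09 for siNR4A2 and siNR4A3. Without edge probes these were -0.052, -0.13 and -0.031, and 1 of the pairs of siNR4A2 and siNR4A3 was above 0 (0.030).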

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

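Some tests were chosen only after the result was seen: those by place on the array for the edge probes and the muscle genes, the test of opposite ends of the array, the test of the muscle genes by slide, and the shuffles of residuals for the interactions.

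In 8 genes the effect of a pool differed with the presence of another, by the test of the difference itself. With siNR4A1 and siNR4A2 the interaction was -0.45 for TNNC1 (adjusted p = 0.00235; 0.00608 with the slide term), -0.36 for MYL1, -0.53 for HSPB3, -0.61 for CR601050, -0.47 for the transcript ENST00000431042 and -0.47 for VAC14-AS1. Among these, TNNC1, MYL1 and HSPB3 are muscle genes that rose with siNR4A2, and the other probe of VAC14-AS1 gave -0.06. With siNR4A2 and siNR4A3 it was -0.51 for NPPB and -0.40 for PKP3 (adjusted p = 0.0320 for both; 0.0233 with the slide term). NPPB rose with siNR4A1 alone and with siNR4A3 alone. The other effects were then kept and the residuals shuffled among the arrays of each slide. For the first interaction, 1 of 100 draws, the real one, reached the 6 genes (highest other 0), and for the second, 1 of 100 reached the 2 genes (highest other 1). The shuffle was run in the main processing alone, where both shares were under 0.05. This argues against chance for the first count. For the second count, of 2 genes, chance is not excluded, since several other settings gave 0 genes. Without 1 array the counts were 1 to 8 and 0 to 3. Median centring gave 3 and 0 genes, no filter on dim probes 1 and 0, and quantile normalisation, the deposited table and normexp 4 and 0, so the second count depends on the processing.

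Most muscle differentiation genes that rose with siNR4A2 had an estimate below the sum of both pools. Of the muscle genes, only TNNC1, MYL1 and HSPB3 passed on their own. Of the 36 members that rose with the siNR4A2 average, 34 had an interaction below 0 (median -0.10). Over the whole list of 46 genes, camera gave adjusted p = 6.15e-12, and adjusted p = 0.0222 with an estimated correlation. List tests had been planned for the comparisons with NT and the averages, not for interactions. The list also holds TNNC1 and MYL1, which passed on their own, so this test is no separate support. Chance values of the NT arrays are argued against: with siNR4A3 present, which uses no NT array, the median was -0.14 (-0.16 to -0.12 over slides). Compression of strong signals stays open, because 44 genes outside the list that rose as much and were as bright had a median of -0.15 (-0.17 to -0.12), against -0.19 for the 16 members that rose by over 0.5. A limit that either pool reaches alone, the biological explanation, cannot be told apart from this: the correlation of the siNR4A1 change with the interaction across members was 0.107 (-0.224 to 0.314 over slides), too wide a range to decide.

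The rise of muscle genes in the 4 groups with siNR4A2 was weighed against place, slide and scaling. Within 1 side of the slide and without edge probes, the smaller of both medians was 0.31 (0.30 to 0.47 over slides), which argues against the edge and the side of the slide. Place within a side and group cannot be told apart, since each group kept its place. The lowest median on a slide was 0.36 (highest 0.41), which argues against a single slide. A factor per array moves all genes alike, but relative to all genes the median was 0.38, and 0.37 with quantile normalisation, the lowest of the scalings (0.35 to 0.43 over slides), which argues against scaling. A response to lower NR4A2 stays open as a hypothesis, as does an effect of the pool on other transcripts, for which no siRNA sequences were at hand.

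Dim probes at the edge of the array moved in the groups of several pools. In these 4 groups the top rows exceeded the bottom rows by 0.24 to 0.49. On slide 1 their values were -0.13 to 0.01, and on slides 2 and 3 they were 0.09 to 0.90, so slide 1 lacked the rise. In the groups on the side of NT the difference was -0.23 to -0.31, and for bright probes it was 0.01 to 0.03 in the 4 groups. Edge probes that passed with a change of over 1 log2 unit gave 110 results for 66 genes, a gene counting once per group. Of these results, 94.1% of 51 in the top rows and 41.2% of 34 in the bottom rows were rises. The difference was 52.9 percentage points (34.8 to 71.1 if the results were independent, which repeated genes are not). Over the 25 results with a probe inside the array, its median change was 19.5% of that at the edge. The central range on redrawing the genes was -1.10% to 52.4%. For 16 of these, the gene did not pass with a change of at least 0.5 in siNR4A2 alone. Over those 16 the median was -0.0093%, so the probes inside did not follow the edge in the median. An effect of place may add to these genes, but place and the number of pools cannot be told apart here, since each group kept its place on all slides.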

How the results depend on the processing

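The tests without edge probes and with normexp background correction of the median signal were chosen only after the results were seen. Of 575 results for named genes, 116 kept the call of the main fit, passing or not, in every setting in which they were fitted. There were 39 settings, and not every result was fitted in each. Where the values below differ from the report, the cause was not tested unless the setting itself shows it. Median centring took the passing genes to 27 in siNR4A1, 320 in siNR4A1+3, 758 and 261 for the siNR4A1 and siNR4A3 averages, 3 and 0 for the interactions of NR4A2 with NR4A1 and with NR4A3, 38 for siNR4A1 against siNR4A3 and 273 for siNR4A1+2+3 against siNR4A2. Quantile normalisation gave 9 genes in siNR4A3, 0 for the interaction of NR4A2 and NR4A3, a passing NR4A2 (-0.49) in siNR4A2, and 4 and 3 lists in siNR4A1+3 and for the siNR4A3 average. The deposited table gave 9 genes in siNR4A3, 0 and 1 for the interactions of NR4A2 with NR4A3 and of all 3, and a passing NR4A2 (-0.49). No filter on dim probes gave 77 genes in siNR4A1, 1 for the interaction of NR4A1 and NR4A2 and 0 for that of NR4A2 and NR4A3. A filter on all 24 arrays gave 10 genes in siNR4A3, 5 lists for the siNR4A3 average, a mean r of 0.49 between backgrounds for siNR4A2 and of -0.061 between siNR4A2 and siNR4A3; rank correlation gave -0.056. The mean of all probes gave a passing NR4A2 of -1.08. A trended robust variance gave 1 gene for the interaction of NR4A2 and NR4A3.

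Replicate block, in which the replicate number is the slide, gave 14 genes in siNR4A3, 990 in siNR4A1+3, 1002 and 4 lists for the siNR4A3 average, 5 and 20 for the interactions of NR4A2 with NR4A3 and of all 3, 1111 for siNR4A1+2+3 against siNR4A2, and a passing NR4A2 (-0.57); it changed the call of no other named gene. Residuals of arrays with the same number had a mean r of 0.412 (81 of 84 pairs over 0.1, lowest 0.0201). For different numbers it was -0.205, which taking out each group's mean pulls below 0. The median share of the sum of squares was 35.9% for the group and 18.6% for the slide. These raw shares make no allowance for there being 8 groups but 3 slides. The group takes the larger share even without any effect, so the shares cannot be ranked. Array weights gave 441, 5699, 258, 4576, 1379, 4443 and 5602 genes in siNR4A1, siNR4A2, siNR4A3, siNR4A1+2, siNR4A1+3, siNR4A2+3 and siNR4A1+2+3, 2766 and 1832 for the siNR4A1 and siNR4A3 averages, 68, 7 and 52 for the interactions of NR4A2 with NR4A1, with NR4A3 and of all 3, 262 and 4559 for siNR4A1 and siNR4A2 against siNR4A3, 3499, 2301 and 3829 for siNR4A1+2+3 against siNR4A1, siNR4A2 and siNR4A3, and passing NR4A2 (-0.57) and NR4A3 (-1.59) in their own groups. A minimum change of 1 log2 unit, which removes genes by construction, left 1, 65, 0, 67, 9, 92 and 86 genes in the 7 groups in the same order, 2, 51 and 12 for the averages, 0 and 0 for the interactions of NR4A2 with NR4A1 and NR4A3, 66, 0 and 65 for siNR4A1 against siNR4A2, siNR4A1 against siNR4A3 and siNR4A2 against siNR4A3, and 72, 13 and 87 for siNR4A1+2+3 against each. A fit to the compared arrays alone, which has fewer arrays to estimate the spread, gave 0, 99, 0, 660, 0, 651 and 999 genes in the 7 groups, 107, 0 and 139 between groups of 1 pool and 357, 0 and 764 for siNR4A1+2+3 against them.

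Normexp gave 42, 8 and 315 genes in siNR4A1, siNR4A3 and siNR4A1+3, 946 for the siNR4A1 average, 0 for the interaction of NR4A2 and NR4A3, 57 for siNR4A1 against siNR4A3, 401 for siNR4A1+2+3 against siNR4A2, 7 and 2 lists in siNR4A1 and siNR4A1+3, and a mean r of -0.16, -0.32 and -0.17 between siNR4A1 and siNR4A2, siNR4A1 and siNR4A3, and siNR4A2 and siNR4A3. It also reversed the oxidative phosphorylation list in siNR4A1+2 (adjusted p = 0.784). Without edge probes those r were -0.052, -0.13 and -0.031, NR4A2 passed at -1.59 in siNR4A2, and another probe of the gene took over for SPRY4 in siNR4A1+2 (0.088), MYH7 in siNR4A1+3 (-0.076), NR4A3 in siNR4A2+3 (0.032) and LDB2 for the siNR4A3 average (0.068), which reversed their direction. With the block as well, the same 4 values resulted, NR4A2 passed at -1.59, and 10 genes in siNR4A3, 760 for the siNR4A3 average and 7 for the interaction of NR4A2 and NR4A3 passed. With an estimated correlation 0, 3, 1, 2, 1, 1 and 3 lists passed in the 7 groups and 3, 2 and 0 for the averages; fry gave 1 in siNR4A1, 1 in siNR4A3, 22 for the siNR4A2 average and 3 for the siNR4A3 average.

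Leaving out 1 array, after which the remaining arrays of a group are assumed to vary like the others, gave 29 to 62, 1514 to 3019, 4 to 6, 1318 to 1432, 197 to 461, 1637 to 1921 and 2022 to 2185 genes in the 7 groups. The averages gave 1165 to 1658, 5529 to 6223 and 234 to 1102, the interactions 1 to 8 (NR4A1 and NR4A2), 0 to 0 (NR4A1 and NR4A3), 0 to 3 (NR4A2 and NR4A3) and 0 to 6 (all 3). Groups of 1 pool differed in 1913 to 3668, 36 to 47 and 1549 to 2323 genes, and siNR4A1+2+3 from them in 1337 to 1556, 332 to 617 and 1413 to 1603. NR4A2 in siNR4A2 ran from -0.76 to -0.37 and NR4A3 in siNR4A3 from -1.68 to -1.49. Lists that passed numbered 7 to 11, 11 to 19, 8 to 21, 11 to 13, 1 to 16, 8 to 16 and 8 to 13 in the groups and 12 to 16, 10 to 14 and 2 to 11 for the averages. The mean r between backgrounds was 0.01 to 0.08, 0.25 to 0.33 and 0.08 to 0.16 for the 3 pools, and between pools -0.17 to -0.044, -0.26 to -0.12 and -0.14 to -0.050. Calls of named genes were lost in 758 of 6654 such fits, against 217 of 397 in the fit to the compared arrays alone, and of 575 in 419 with a minimum change of 1 log2 unit, 106 under normexp, 86 under median centring, 44 without a filter, 38 under quantile normalisation, 37 in the deposited table and at most 26 in each other setting. Normexp on the mean signal was not run, since the files lack that column, a block by slide equals the replicate block, and a fit to the compared arrays gives no other value for averages and interactions. Signal over background limits NR4A1, dim on all 24 arrays, and every fold given as a lower limit.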

Other observations

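The swaps within slides, the shuffles of residuals and the splits for a pool added to others were chosen only after the results were seen, as were the genes in the next 2 paragraphs.

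The siNR4A2 pool lowered DICER1, which encodes the enzyme that processes microRNA precursors. DICER1 fell by 0.89 in siNR4A2 against NT (adjusted p = 3.63e-07), by 1.03 in siNR4A1+2, by 0.98 in siNR4A1+2+3 and by 0.96 on average over the 4 backgrounds (adjusted p = 1.31e-12). Of the 13 small RNA pathway genes tested, 2 rose, 3 fell and 8 did not pass with the siNR4A2 average (3 rose and 3 fell when adjusted over the list alone). With the siNR4A1 average 4 rose, 0 fell and 9 did not pass (5 rose when adjusted over the list alone), and with the siNR4A3 average 2 rose, 0 fell and 11 did not pass (3 rose when adjusted over the list alone). The list's camera adjusted p was 0.578, 0.00302 and 0.0496 for these averages, and 0.810, 0.0883 and 0.623 with an estimated correlation. The call for siNR4A1 was lost under normexp (0.0708), and that for siNR4A3 with the slide term (0.103) and in 16 of the 24 fits that leave out 1 array.

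The siNR4A2 pool also raised regulators outside the muscle list. On average over the backgrounds, the transcription factor SNAI1 rose by 1.02 (adjusted p = 8.4e-14), the cell death genes BMF by 0.99 (adjusted p = 4.86e-14) and BCL2L11 by 0.42, the lysosomal sialidase NEU1 by 0.93 and the nuclear receptor NR0B1 by 0.93 (adjusted p = 2.53e-06).

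The count of genes of each comparison was set against other divisions of the same arrays. For the average effects, with a pool's label shuffled within each background, the real count was reached in 1 of 100 draws for siNR4A1 (1503 genes; highest other 9), in 1 of 100 for siNR4A2 (5948; highest other 1765) and in 2 of 100 for siNR4A3 (447; highest other 1020). These draws do not hold the slide fixed: the one of 1020 genes, over the real 447, had 4, 1 and 7 of its 12 labels on the 3 slides, and that of 1765 genes had 2, 3 and 7, where the real labels have 4 on each. With labels swapped only within a background and slide, and the slide as a blocking term, 1 of 100 draws, the real one, reached the real count for each pool. The counts were 2158 genes for siNR4A1 (highest other 684), 6980 for siNR4A2 (highest other 3479) and 1002 for siNR4A3 (highest other 43). This argues against chance for the 3 averages at a share of 0.05, by a swap chosen after the results were seen. For siNR4A3 the count itself ran from 234 to 1102 on leaving out 1 array. The swap does not test an effect of place, since each group kept its place on all slides. With the other effects kept and residuals shuffled within each slide, 100 of 100 draws reached the 0 real genes for the interaction of NR4A1 and NR4A3 (highest other 1) and for that of all 3 (highest other 0), since every draw passes at least 0 genes.

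For comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. In each but that of siNR4A3 added to siNR4A2, 1 split, the real one, reached the real count. The real count and the highest of the other splits were 120 and 0 in siNR4A1 against NT, 2505 and 1 in siNR4A2, 5 and 1 in siNR4A3, 1945 and 1 in siNR4A1+2, 621 and 1 in siNR4A1+3, 2389 and 0 in siNR4A2+3, and 2823 and 0 in siNR4A1+2+3. Between groups of 1 pool they were 3136 and 0 for siNR4A1 against siNR4A2, 90 and 0 for siNR4A1 against siNR4A3, and 2300 and 1 for siNR4A2 against siNR4A3. For siNR4A1+2+3 they were 2064 and 0 against siNR4A1, 667 and 0 against siNR4A2, and 2021 and 0 against siNR4A3. For siNR4A1 added to siNR4A2, siNR4A3 or both they were 110 and 1, 102 and 0, and 93 and 0. For siNR4A2 added to siNR4A1, siNR4A3 or both they were 1813 and 0, 2139 and 0, and 1647 and 1. For siNR4A3 added to siNR4A1 or to siNR4A1+2 they were 5 and 0, and 25 and 0. Added to siNR4A2 alone it passed 2 genes, and 2 of the 10 splits, the real one included, passed as many (highest other 2).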
